A study of Mus musculus with 24 samples.

How the data were processed

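Liver RNA of male C57BL/6J mice was measured in 24 samples with an Illumina bead array after conversion to biotin-labelled cRNA with Ambion kits. The mice were 16 weeks old and had been fed for 10 weeks in 4 groups of 6: control (normal diet, plain water), high-sugar (normal diet, a drink with 23% w/v sugar), high-fat (high-fat diet, plain water) and high-fat high-sugar (high-fat diet, sugar drink). The labels number the replicates from 1 to 6 and do not state that each came from a separate animal, so the p-values measure the spread between these 24 samples. Per the labels, the authors made the values with GenomeStudio 2011.1. The deposited unit is the intensity of each of 45281 probes on a linear scale. The values were already background-subtracted, since 37.7% were negative and the lowest was −13.0. They were also quantile-normalised, since the largest difference between sorted columns was 0.231, and the column medians lay between 2.70 and 2.74. These 2 properties were read from the values.

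A deposited table of non-normalised values holds 24 signal and 24 detection p columns whose names could not be matched to samples, so it was not used here. The fit fixed before the data were examined was to start from that table with background correction and detection p-values. The normalised intensities took its place, and this choice was made after the data were seen. An offset of 32 was added to each intensity and log2 taken. The offset shrinks fold changes of dim genes, so every fold is a fold of intensity plus offset. Values of named genes moved by over 1.5-fold, none in sign, in 10 cases with an offset of 16 (all larger in size), 9 with 64 (all smaller) and 42 with a floor of 16 (all larger). With either offset these were of Cyp2b9, Cyp2b13, Cyp2b23, Gsta1, A1bg, Atf3 and Fos, as for Cyp2b23 with both treatments (4.41, against 5.34 with 16 and 3.50 with 64). With the floor, further genes were Cyp2b10, Cyp2c29, Ugt1a2, Ugt1a5, Dnajb9, Srebf1, Gpnmb, Timp1, Cidec, Cdc20, Ly6d, Pck1, ND4L, Mmp13 and Ccl4.

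The noise SD of an array was the root mean square of its negative values, mirrored at 0. A probe was kept when it exceeded 1.645 noise SD (an intensity of 6.50 to 6.52) on at least 6 of the 24 arrays, whatever the group. This left 20216 probes, of which 16910 had 1 gene symbol and 3306 had not. Where a gene had several probes, as 4030 genes did, the probe with the highest mean over all arrays was taken, which gave 11115 genes. Other probes that passed in the same direction could give smaller changes, as for Usp2 and A1bg, and are mostly not printed. On each array between 17976 and 18010 probes lay above the noise limit, a narrow range that the quantile normalisation forces, and the number of arrays limits the precision. A group compared averaged under the highest limit for 292 of the 3208 genes changed by sugar on the normal diet, 310 of 3399 on the high-fat diet, 113 of 1985 by fat with water, 69 of 873 with sugar, 24 of 270 in the interaction and 326 of 3945 with both treatments. For such genes the mean intensity is given in place of a fold, or, in the interaction, the log2 value with this limit stated. Symbols came from the array's annotation and were brought up to date by gene identifier for 34807 of 34885 probes with 1 symbol. For 78 probes the array's own symbol was kept. Another 10378 probes had no symbol and 18 had several. No genome build is given for the array in the sources used here, so no coordinates are printed.

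Tests used limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group, and empirical Bayes moderation with an intensity trend (20 residual and 6.96 prior degrees of freedom). The 6 contrasts came from 1 fit: the sugar drink on each diet, the high-fat diet with each drink, the interaction (the sugar effect on the high-fat diet minus that on the normal diet), and both treatments together against control. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with 0.05 as the threshold, and "rose", "fell" and "changed" refer to it. The SE is that of the moderated fit on the log2 scale, with n = 6 per group. In 25 lists of genes fixed before the data were examined, camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the 25 lists. It was run again with an estimated correlation (0.016 to 0.57, by list), under which no list passed in any contrast. Members were also counted with p adjusted over the list alone. Effects were compared across genes by Pearson's r and Spearman's rho, and genes are not independent replicates.

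The genes to be named were fixed by a rule before the data were examined: the 8 largest rises and 8 largest falls among passing genes with a standard symbol, and in each list the 4 members with the smallest adjusted p, taken in that order where fewer are printed. The rule named 647 gene and contrast pairs. Of these, 242 pairs, of 137 genes, were followed for stability, and that of the others was not tested. A few further list members are named under the same rule. Probes of near-identical families (Cyp2b, Ugt1a, Mup, Cyp4a12, Gsta, Serpina1, Orm and Saa genes) can take up signal from relatives, so which member changed is uncertain there.

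The pipeline was tested on simulated data, drawn around each gene's mean with its residual spread, with known shifts added to the high-sugar group. It recovered 56 of 67 genes shifted by 0.5 (log2), 66 of 67 shifted by 1 and 66 of 66 shifted by 2, and 18 of 20 members of a list shifted by 0.5, with 15 false calls among 221 (6.79%). Samples with the same number in different groups were no closer than others (mean correlation of deviations 0.013 against −0.0025), so the numbers were not treated as pairs. The slide and array position of each sample are not given in the sources used here. A difference in hybridisation that follows the groups therefore cannot be told apart from them. Alternatives varied the filter, the offset, a floor in place of it, the normalisation, the moderation, array weights, the replicate number as a block, all probes, only the compared groups, and each sample left out. The closing section gives their effect.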

Results

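Hepatic gene expression was profiled in male mice that drank plain water or a 23% (w/v) sugar drink on a normal or a high-fat diet for 10 weeks. The 24 samples formed 4 groups of 6, and 11115 genes were tested. All arrays had nearly the same distribution of intensities, with between 17976 and 18010 probes above the noise limit per sample. The quantile normalisation of the deposited values forces this, so it does not show that the arrays were of equal quality. Correlations between samples of a group lay between 0.987 and 0.996, and those between groups between 0.974 and 0.992. The study asks how a high sugar intake changes liver transcription on a normal and on a high-fat diet. All comparisons below are between groups of 6 samples, errors are standard errors on the log2 scale (n = 6 per group), and folds are of intensity plus the offset of 32. No fold is given against a group whose mean intensity lay under the noise limit.

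**Figure D1:**
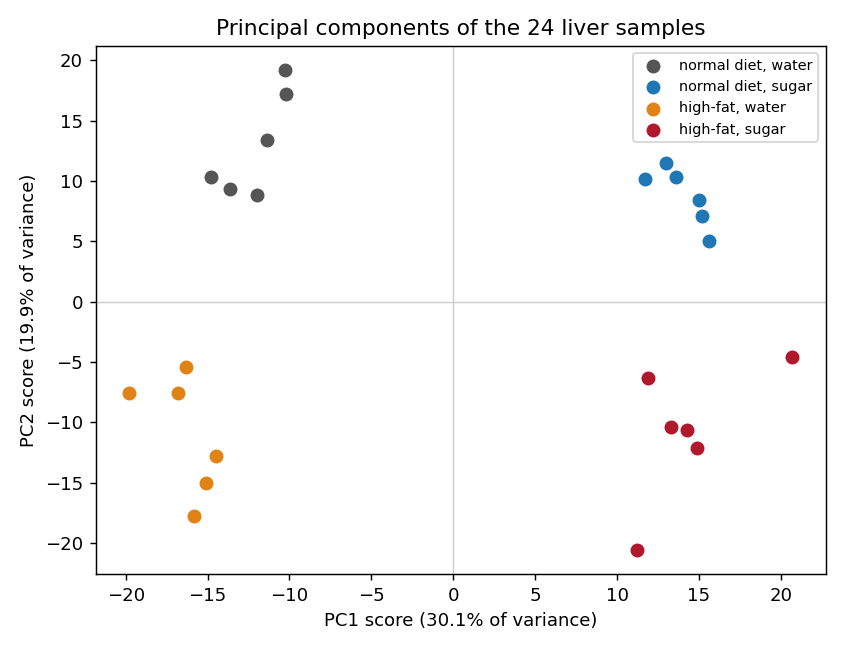
Principal components of the 11115 genes (log2 intensity), 1 dot per sample, coloured by group (n = 6 each), with the share of variance on each axis in percent. The first axis (30.1%) parted the sugar-drink samples, all at 11.2 or above, from the water samples, all at −10.2 or below, and the second (19.9%) parted the diets, with normal-diet samples at 5 or above and high-fat samples at −4.6 or below.

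The first comparison asks what the sugar drink changed on the normal diet (high-sugar against control). Of genes of fatty acid synthesis, 2 were among the largest falls: Scd1, the stearoyl-CoA desaturase, was 5.65-fold lower (−2.50 ± 0.29), and Acacb, an acetyl-CoA carboxylase, 2.74-fold lower (−1.45 ± 0.14). Elovl6, a fatty acid elongase, was 2.02-fold lower and Fads2, a desaturase, 1.52-fold lower. Of interferon-response genes, Gbp2 was 2.13-fold (1.09 ± 0.19), Ifit3 2.02-fold and the chemokine Cxcl10 1.92-fold higher. Among cytochrome P450 genes, Cyp2b9 rose 19.4-fold (4.28 ± 0.60), Cyp2b23 from under the noise limit to a mean intensity of 192 and Cyp2c50 3.46-fold, with the reservation that probes of this family can take up each other's signal. Of the 11115 genes, 3208 changed, 1649 higher and 1559 lower, and 468 of them by at least 1.5-fold (310 higher, 158 lower).

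Other large rises on the normal diet were those of Aatk, a kinase (4.53-fold, 2.18 ± 0.14), Egr1, an immediate early transcription factor (3.32-fold), and Nrep (2.73-fold). Cib3 was 6.80-fold lower (−2.77 ± 0.37), Ugt1a2 4.23-fold, Ugt1a5 3.83-fold and Cyp4a12b 3.58-fold, the last 3 from families of near-identical genes. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, was 3.09-fold lower (adjusted p = 0.0196). Adjusted p for the other genes of this paragraph ran from 6.14e-11 (Aatk) to 0.00333 (Nrep). For all 39 genes followed in this comparison, 6 of 6 high-sugar samples lay on the same side of the control mean. The genes followed were picked from these same samples by their change or p. Such counts, here and in the comparisons below, therefore follow largely from the selection and are no separate evidence.

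Interferon-response genes as a list rose with the sugar drink on the normal diet: 8 of 14 measured members rose, 0 fell and 6 did not pass, with a median of 0.49 and the same 8 when adjusted over the list alone (adjusted p = 0.00627, but adjusted p = 0.698 with an estimated correlation). In the xenobiotic list 9 of 19 rose, among them Cyp2c29 (1.72-fold), Cyp2c37 (2.29-fold) and Cyp2b10 (2.28-fold, on 1 of its probes, while another gave 0.12), and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.0303, and adjusted p = 0.698 with an estimated correlation). The Cyp2c29 probe was dim, at mean intensities of 15.6 in control and 50.2 in high-sugar samples. It may therefore not reflect the level of the transcript. Of 17 genes of the unfolded protein and integrated stress response, 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0103, and adjusted p = 0.538 with an estimated correlation). These included the chaperones Dnajb9 (2.15-fold) and Calr (1.96-fold) and the disulfide isomerase Pdia6 (1.40-fold). Among 14 NRF2 and antioxidant genes, 6 rose and 0 fell, the same when adjusted over the list alone (adjusted p = 0.0303, and adjusted p = 0.355 with an estimated correlation), with Gclm, which takes part in glutathione synthesis, 1.74-fold and catalase (Cat) 1.67-fold higher. Of 13 genes of bile acid synthesis and sterol export, 5 rose and 0 fell, the same when adjusted over the list alone (adjusted p = 0.0103, and adjusted p = 0.538 with an estimated correlation). Baat, which conjugates bile acids, was 1.73-fold higher, the bile salt export pump Abcb11 1.34-fold and the uptake carrier Slco1b2 1.27-fold.

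The remaining lists did not pass on the normal diet, though single members did. De novo lipogenesis had 5 of 17 members lower and 1 higher (adjusted p = 0.107). For gluconeogenesis and glycogen, 4 of 13 fell and 1 rose (adjusted p = 0.5), with a median of 0.02 and a mean of −0.22. There Ppargc1a, a coactivator of gluconeogenic genes, was 1.94-fold lower and pyruvate carboxylase (Pcx) 1.57-fold lower, while another Pcx probe gave −0.02. Of 26 fatty acid oxidation genes and PPAR alpha targets, 7 rose and 1 fell (adjusted p = 0.107), with Acadm 1.37-fold and Hadhb 1.86-fold higher. In cholesterol synthesis 6 of 18 rose and 1 fell (adjusted p = 0.107), with Ebp 1.74-fold higher. Markers of other cells did not pass as lists. The macrophage markers Mpeg1 and Adgre1 rose from under the noise limit to mean intensities of 19.96 and 8.06, 2 of 12 in that list (adjusted p = 0.5). With intensities under 16 set to 16 these 2 calls ended, at 0.37 and 0.00. Of 11 endothelial markers 4 rose and 2 fell (adjusted p = 0.891, median −0.06, mean 0.01), with Clec4g 0.32 ± 0.08 on 1 probe and −0.16 on another, and Eng −0.32 ± 0.08. Amy2a5, an amylase gene of the pancreas list, was 1.67-fold higher (2 of 5 members rose, adjusted p = 0.532). Probes of 1 gene did not always move together here: of 723 second probes that passed for changed genes, 121 (16.7%) went in the opposite direction, against 2 of 472 (0.424%) for the high-fat diet with water. For the 11 other probes of the genes followed in this comparison, 8 passed in the same direction and 3 did not pass.

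The next comparison asks what the sugar drink changed on the high-fat diet (high-fat high-sugar against high-fat). Acacb was 3.37-fold lower (−1.75 ± 0.14), Scd1 3.23-fold lower and Fads2 2.00-fold lower, while Srebf1, a transcription factor of lipid synthesis, was 1.90-fold higher (0.93 ± 0.13) and Dgat2, which forms triglyceride, 1.60-fold higher. Of the stellate and fibrosis list, which did not pass (3 of 13 rose, adjusted p = 0.179), Timp1 rose 2.65-fold (1.41 ± 0.24), Col1a1 by 0.71 ± 0.19 (log2) and Mmp13 from under the noise limit to a mean intensity of 56.7. Another Mmp13 probe gave −0.06. The macrophage gene Gpnmb rose 3.12-fold (SE 0.32, in 5 of 6 samples above the high-fat mean) and the cytokine gene Il1b 2.01-fold. In all, 3399 genes changed, 1839 higher and 1560 lower, 669 of them by at least 1.5-fold (483 higher, 186 lower).

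The largest rises on the high-fat diet were those of Cyp2b9 (6.67-fold, 2.74 ± 0.60, but 1.995 without high-fat replicate 5), Aatk (5.49-fold), Cyp2b13, Gsta1, Cyp2b23 (4.48-fold) and Plin4, a lipid droplet protein gene (4.12-fold). Cyp2b13 and Gsta1 rose from under the noise limit to mean intensities of 190 and 184. Eif4ebp3 was 7.92-fold lower (−2.99 ± 0.38), Ugt1a5 6.48-fold, Ugt1a2 6.00-fold, Cyp4a12b 4.12-fold, A1bg 3.69-fold and the steroid hydroxylase gene Cyp17a1 3.64-fold. The Cyp2b, Gsta, Ugt1a and Cyp4a12 values carry the uncertainty of near-identical genes. Their adjusted p ran from 3.17e-12 (Aatk) to 0.000895 (Cyp2b9). Apart from Gpnmb, all 47 genes followed in this comparison lay on the same side of the high-fat mean in 6 of 6 samples.

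In the xenobiotic list 11 of 19 members rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 4.31e-05, and adjusted p = 0.282 with an estimated correlation), with Cyp2a5 3.61-fold (1.85 ± 0.16), Cyp2c37 2.52-fold and Cyp1a2 2.26-fold higher. In the unfolded protein list 9 of 17 rose and 1 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.561 with an estimated correlation), with Hsp90b1 2.39-fold and Dnajb9 2.14-fold higher and Atf3 up from under the noise limit to a mean intensity of 20.6. Of 8 immediate early genes, 4 rose and 0 fell, the same when adjusted over the list alone (adjusted p = 0.0464, and adjusted p = 0.645 with an estimated correlation), with Jun (2.06-fold), the phosphatase Dusp1 (1.72-fold) and Fos (from under the noise limit to a mean intensity of 27.5) among them. Bile acid synthesis and sterol export had 5 of 13 members higher and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0464, and adjusted p = 0.561 with an estimated correlation). The sterol transporters Abcg8 (1.70-fold) and Abcg5 (1.53-fold) and the bile salt pump Abcb11 (0.71 ± 0.10 on the log2 scale) were among those that rose.

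Further lists did not pass on the high-fat diet. Fatty acid oxidation genes and PPAR alpha targets had 8 of 26 lower and 3 higher (adjusted p = 0.135), with Crat 1.71-fold lower. Cpt1a, the carnitine acyltransferase of mitochondrial entry, fell from a mean intensity of 31.2 to 6.48, under the noise limit. The Cpt1a probe was dim in all 4 groups (31.2 or less), so it may not reflect the level of the transcript. Acot2 was 2.03-fold lower on 1 probe, while 2 others gave −0.04 and −0.06. Lipid droplet genes had 7 of 16 lower and 4 higher (adjusted p = 0.148), with Plin5 2.23-fold and the lipase Pnpla2 1.61-fold lower. De novo lipogenesis had 5 of 17 lower and 4 higher (adjusted p = 0.208). In amino acid catabolism and the urea cycle 7 of 12 fell and 1 rose (adjusted p = 0.0698), with Asl 2.13-fold lower, Cps1 lower (−0.59 ± 0.12) and Prodh 1.74-fold higher (another Prodh probe gave 0.35). Gclm was 2.03-fold higher (NRF2 list: 5 of 14 rose, 1 fell, adjusted p = 0.062), and Gbp2 2.31-fold and Cxcl10 2.32-fold (interferon list: 6 of 14 rose, 0 fell, adjusted p = 0.0911). Cholesterol synthesis had 5 of 18 higher and 1 lower (adjusted p = 0.0703) and the clock list 5 of 13 higher and 0 lower (adjusted p = 0.0911). Beside these, 4 of 12 macrophage markers rose and 1 fell (adjusted p = 0.135), 3 of 13 stellate and fibrosis markers rose (adjusted p = 0.179), and 3 of 11 endothelial markers fell and 1 rose (adjusted p = 0.536), with Stab2 lower (−0.58 ± 0.09). Amy2a5 was 1.78-fold higher (pancreas list: 1 of 5 rose, 1 fell, adjusted p = 0.516). Of second probes that passed, 137 of 794 (17.3%) moved against the gene's other probe, while for the genes followed 17 of 21 other probes passed in the same direction and 4 did not pass.

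Across the 11115 genes, the sugar effects on both diets were correlated (Pearson's r = 0.684, Spearman's rho = 0.615), and 71.6% had the same sign. Both comparisons called 1030 genes higher, where independent calls would share 272.8, and 674 lower, where 218.8 would be shared, while 28 genes were called in opposite directions. The effects of the high-fat diet with water and with the sugar drink were correlated at r = 0.525 (rho = 0.37), with 60.2% of genes of the same sign, 179 genes higher in both (43.67 if independent), 170 lower in both (34.4) and 8 opposite. These are correlations across genes, and the groups of a pair share no samples. A hybridisation difference that followed the drink or the diet would still be shared by both effects of a pair. The correlations cannot tell it from the treatment. Second probes that passed went the opposite way in 16.7% and 17.3% of cases for sugar on the normal and high-fat diet. For the high-fat diet with water and with sugar the shares were 0.424% and 1.71%.

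**Figure D2:**
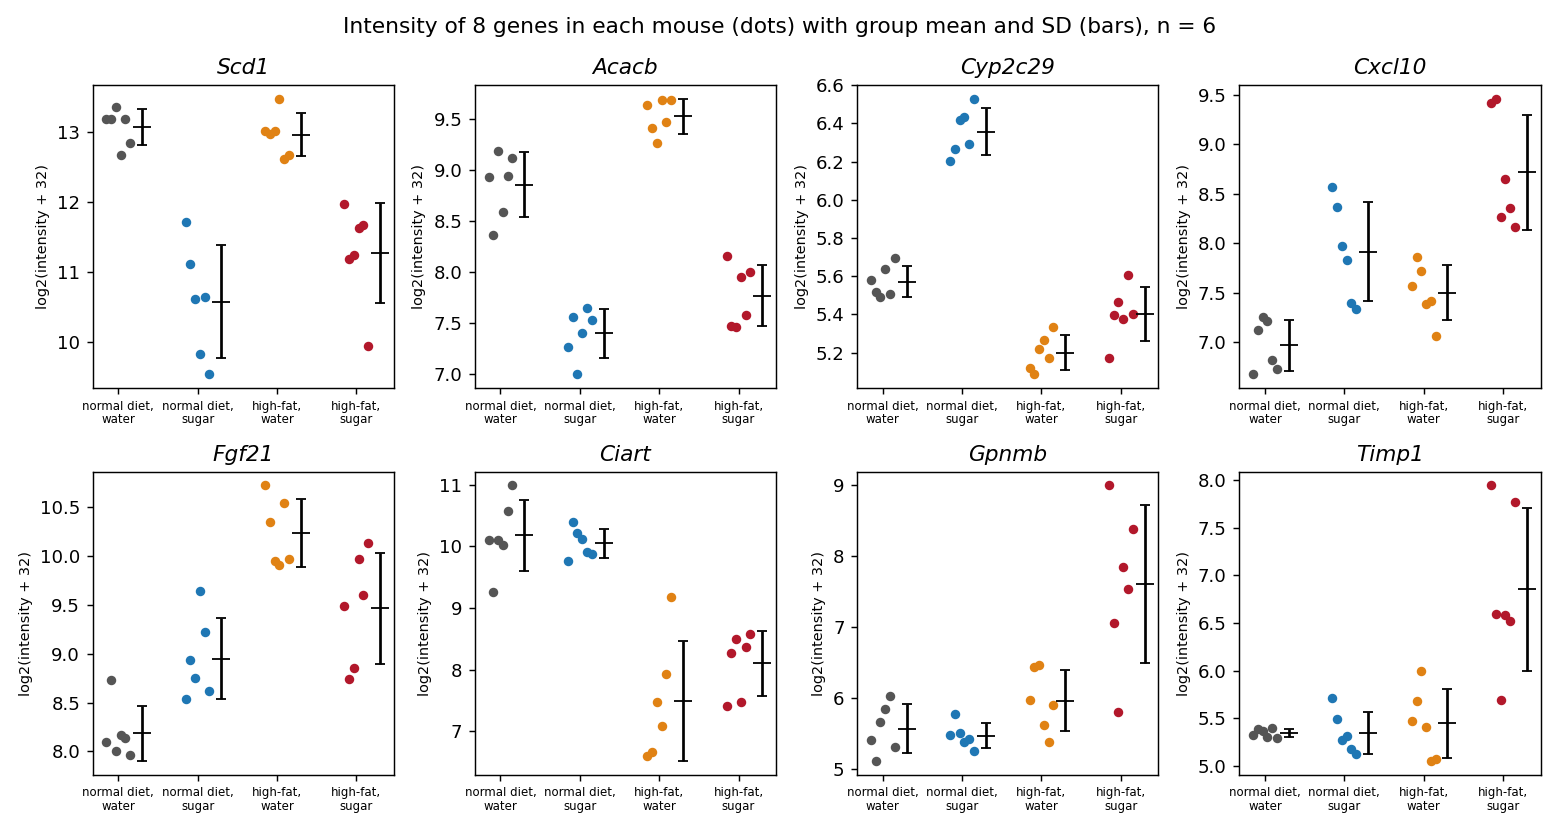
Intensity of 8 genes in each sample (log2 of intensity plus 32 on the vertical axis, dots) by group (n = 6 each, horizontal axis), with group means and SD as bars. Scd1 averaged 13.07 in control and 10.57 in high-sugar samples, Ciart 10.18 in control and 7.49 in high-fat samples, and Gpnmb 7.61 in high-fat high-sugar samples against 5.96 or less in the other groups. The Cyp2c29 probe was dim in all 4 groups, at a mean intensity of 50.2 or less.

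The comparison of the diets with plain water (high-fat against control) asks what the high-fat diet changed on its own. Of genes of the circadian clock list, Ciart, a clock repressor, was 6.46-fold lower (−2.69 ± 0.32), the protease gene Usp2 3.93-fold, Tef 1.96-fold and Per2 1.89-fold. Of 2 other Per2 probes, 1 passed (−0.70) and 1 did not (−0.12). Of lipid storage genes, Cidec was 2.66-fold (1.41 ± 0.23), the apolipoprotein gene Apoa4 2.98-fold and Plin2 2.00-fold higher. The hormone gene Fgf21 rose 4.15-fold (2.06 ± 0.21) and Acnat2, an acyltransferase, 4.02-fold. Thrsp and Lpin1, both of lipid synthesis, were 4.70-fold (−2.23 ± 0.27, but −0.66 on another probe) and 4.18-fold lower. In all, 1985 genes changed, 1007 higher and 978 lower, and 354 by at least 1.5-fold (177 higher, 177 lower). More were lower than higher with cyclic loess (931 higher, 1054 lower) and with array weights (1000 and 1006).

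Among the largest rises with the high-fat diet and water were also Cyp2b9 (11.3-fold, 3.50 ± 0.60, but 4.24 without high-fat replicate 5), Lcn2, an acute phase gene (5.27-fold, 2.40, but 1.79 without high-fat replicate 3, adjusted p = 0.0254), Ly6d (4.79-fold), and A1bg and Cyp2b23, both from under the noise limit to mean intensities of 155 and 176. Among the falls were Hsd3b5, a male-biased steroid dehydrogenase gene (4.29-fold lower, −2.10 ± 0.63), and Rgs16 (3.97-fold lower). Adjusted p for the largest changes ran from 8.17e-08 (Usp2) to 0.0209 (Hsd3b5), and the Hsd3b5 call ended without replicate 5 of the high-fat group (−1.72, adjusted p = 0.0611) and with a floor of 16. Of the 44 genes followed, 40 lay on the same side of the control mean in 6 of 6 high-fat samples and 4 (Cyp2b9, Cyp2b23, Vsig4 and Clec4f) in 5 of 6.

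The circadian clock list passed as lower with the high-fat diet and water: 9 of 13 members fell, 4 did not pass and 0 rose, or 9 and 1 adjusted over the list alone, with a median of −0.67 (adjusted p = 9.64e-07, and adjusted p = 0.0808 with an estimated correlation). Of 26 fatty acid oxidation genes and PPAR alpha targets, 9 rose and 0 fell, or 15 and 0 adjusted over the list alone (adjusted p = 3.65e-06, and adjusted p = 0.19 with an estimated correlation). Besides Fgf21, Cpt1a was higher (0.58 ± 0.11, on a dim probe with mean intensities of 10.1 and 31.2). Acot2 was 2.71-fold higher on 1 probe (0.00 and −0.07 on 2 others). Lipid storage and droplet genes had 8 of 16 higher and 0 lower, or 9 and 0 adjusted over the list alone (adjusted p = 7.28e-06, and adjusted p = 0.0808 with an estimated correlation). Of 18 genes of cholesterol synthesis and uptake 8 fell and 0 rose, or 13 and 0 adjusted over the list alone (adjusted p = 3.72e-05, and adjusted p = 0.224 with an estimated correlation), with Msmo1 2.27-fold, Stard4 1.93-fold and Srebf2 1.57-fold lower (another Srebf2 probe gave 0.07). In the xenobiotic list 10 of 19 fell and 0 rose, the same when adjusted over the list alone (adjusted p = 7.28e-06, and adjusted p = 0.0808 with an estimated correlation), among them Cyp2a5 (3.21-fold lower, −1.68 ± 0.16), Gsta4 (2.06-fold) and Cyp1a2 (2.04-fold). Gluconeogenesis and glycogen had 4 of 13 members lower and 0 higher, or 7 and 0 adjusted over the list alone (adjusted p = 0.00278, and adjusted p = 0.224 with an estimated correlation). Ppp1r3b was 2.42-fold lower, Pygl, the liver glycogen phosphorylase, 1.56-fold, and Pck1, of gluconeogenesis, 1.79-fold (another Pck1 probe gave −0.24 and did not pass). In de novo lipogenesis 4 of 17 fell and 3 rose, or 6 and 3 adjusted over the list alone (adjusted p = 0.0307, and adjusted p = 0.382 with an estimated correlation), with Srebf1 2.00-fold and Dgat2 1.71-fold lower.

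The interferon list also passed as higher with the high-fat diet and water: 6 of 14 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 6.76e-05, and adjusted p = 0.304 with an estimated correlation), with Usp18 2.08-fold and Oasl2 1.40-fold higher (another Oasl2 probe gave −0.03). Of 12 cell cycle genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.00706, and adjusted p = 0.32 with an estimated correlation), with Cdc20 2.47-fold and cyclin D1 (Ccnd1) 1.95-fold higher. Macrophage and Kupffer cell markers had 5 of 12 higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 0.00706, and adjusted p = 0.33 with an estimated correlation), with Vsig4 1.39-fold and Clec4f 1.34-fold higher, while another Clec4f probe gave 0.07. Acute phase genes had 3 of 17 higher and 1 lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.471 with an estimated correlation), with the probe of fibrinogen beta (Fgb) up from under the noise limit to a mean intensity of 17.9, a call that ended with a floor of 16. This probe averaged 17.9 or less in all 4 groups, near background, so it may not reflect the level of the transcript. Stellate and fibrosis markers had 2 of 13 higher, the same when adjusted over the list alone, and 0 lower (adjusted p = 0.0303, and adjusted p = 0.451 with an estimated correlation). These were Lum (1.55-fold, a call lost without control replicate 1, adjusted p = 0.056, or 6, adjusted p = 0.0505) and Vim (1.44-fold, lost without any of 6 samples, with adjusted p up to 0.115, with no filter, adjusted p = 0.0548, and with a floor of 16, adjusted p = 0.0749). Endothelial markers had 2 of 11 higher, Clec4g (1.28-fold, another probe 0.06) and Stab1 (1.35-fold, other probes 0.36 and −0.07, not passing without control replicate 6, adjusted p = 0.0534), with adjusted p = 0.25 for the list. In bile acid synthesis and sterol export 3 of 13 fell and 2 rose (adjusted p = 0.117), with Abcg8 1.61-fold and Cyp27a1 1.52-fold lower.

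**Figure D3:**
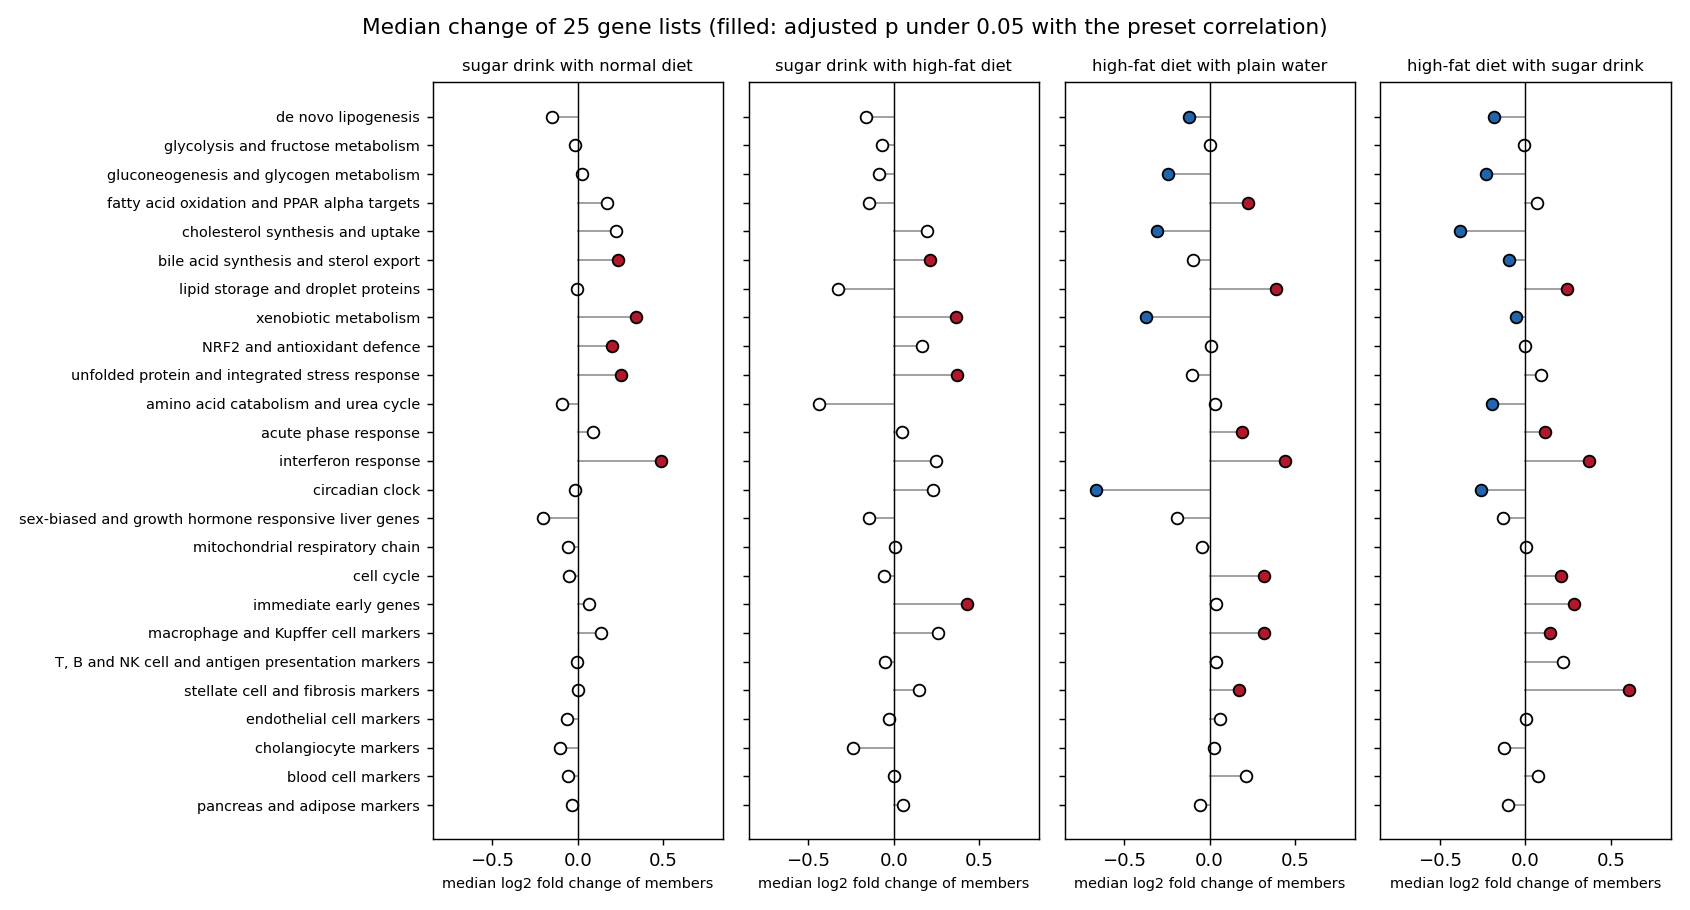
Median log2 fold change of the measured members of 25 gene lists (horizontal axis, 1 dot per list) in 4 comparisons of 6 against 6 samples. Filled dots passed at an adjusted p under 0.05 with the preset correlation, red upward and blue downward, and none passed with an estimated correlation. The clock list lay at −0.67 with the high-fat diet and water, and the stellate and fibrosis list at 0.61 with the high-fat diet and sugar drink.

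The comparison of the diets with the sugar drink (high-fat high-sugar against high-sugar) asks what the high-fat diet changed where sugar was drunk. Gpnmb rose 4.39-fold (2.13 ± 0.32), Timp1 2.84-fold (SE 0.24), Il1b 2.20-fold and Col1a1 1.83-fold. Lpin1 was 5.39-fold lower (−2.43 ± 0.35), Thrsp 4.73-fold (−1.46, log2, on another probe) and Ciart 3.86-fold, as with water. Pck1, of gluconeogenesis, was 2.67-fold lower (−1.42 ± 0.10). In all, 873 genes changed, 482 higher and 391 lower, and 248 by at least 1.5-fold (136 higher, 112 lower). Of all probes, 671 were higher and 754 lower. Without replicate 1 of the high-fat high-sugar group the count was 534.

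Other large changes with the high-fat diet and the sugar drink were rises of Ly6d (7.71-fold, 2.95 ± 0.41), Lcn2 (3.96-fold), Cyp2b9 (3.88-fold), Cyp2b13 (3.77-fold) and Orm2 (3.63-fold), and falls of Hsd3b5 (8.64-fold lower, −3.11 ± 0.63, but −2.51 without high-fat high-sugar replicate 1), Serpina1e (5.61-fold), Rgs16 (5.21-fold) and Mup5 (4.76-fold). The Cyp2b, Orm, Serpina1 and Mup values carry the uncertainty of near-identical genes. Adjusted p ran from 4.3e-08 (Mup5) to 0.0482 (Lcn2). The Lcn2 call was lost without any of 15 of the 24 samples (adjusted p up to 0.128), with the replicate block (0.0741), without the trend (0.0525), with no filter (0.0549) and with a floor of 16 (0.11). That of Cyp2b9 was lost without any of 7 samples (adjusted p up to 0.108), with an offset of 16 (0.0646) and with a floor of 16 (0.181). Of the 45 genes followed, 42 lay on the same side of the high-sugar mean in 6 of 6 samples, and none in fewer than 5.

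Stellate and fibrosis markers rose as a list with the high-fat diet and the sugar drink: 7 of 13 rose and 0 fell, or 8 and 0 adjusted over the list alone, with a median of 0.61 (adjusted p = 1.08e-07, and adjusted p = 0.161 with an estimated correlation). Col4a1 was 1.66-fold higher, and Mmp13 2.06-fold on 1 probe, while another gave 0.04. Macrophage markers had 5 of 12 higher and 0 lower, the same when adjusted over the list alone (adjusted p = 0.000168, and adjusted p = 0.161 with an estimated correlation), with Lyz2 1.87-fold (another probe 0.03) and Cd14 1.79-fold higher. Beside them, 0 of 11 endothelial markers passed (median 0.01, adjusted p = 0.812). Interferon-response genes had 1 of 14 higher, Cxcl10 (1.75-fold), and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.00206, and adjusted p = 0.315 with an estimated correlation). The Cxcl10 call was lost without high-fat high-sugar replicate 1 (adjusted p = 0.0727) or 2 (0.0604), without high-sugar replicate 5 (0.0631) or 6 (0.061), in a fit of these 2 groups alone (0.0563) and with a floor of 16 (0.058). Acute phase genes had 3 of 17 higher and 0 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.354 with an estimated correlation), with Orm1 1.52-fold higher. Cell cycle genes had 2 of 12 higher, Ccnd1 (1.79-fold) and Mcm2 (1.44-fold), and 0 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.00943, and adjusted p = 0.283 with an estimated correlation). Of 8 immediate early genes 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.0404, and adjusted p = 0.329 with an estimated correlation), with Fos at mean intensities of 6.48, under the noise limit, and 27.5, a call that ended with a floor of 16. The neutrophil gene S100a9, of the blood cell list, rose from under the noise limit to a mean intensity of 12.3 (1 of 6 rose, adjusted p = 0.213), a call that a floor of 16 ended too (0.09). Cela1, of the pancreas list, was 1.62-fold lower (1 of 5 fell, adjusted p = 0.0704).

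Of metabolic lists, fatty acid oxidation and PPAR alpha targets (1 of 26 rose, 0 fell, adjusted p = 0.684), glycolysis and fructose (1 of 9 rose, 2 fell, adjusted p = 0.633) and the respiratory chain (0 of 18 rose, 1 fell, adjusted p = 0.812) did not pass with the high-fat diet and the sugar drink. Cholesterol synthesis and uptake had 6 of 18 lower and 0 higher, or 7 and 0 adjusted over the list alone (adjusted p = 3.23e-06, and adjusted p = 0.161 with an estimated correlation), with Insig1 1.75-fold, Lss 1.46-fold (another probe 0.07) and Tm7sf2 1.30-fold lower. Gluconeogenesis and glycogen had 5 of 13 lower and 0 higher, the same when adjusted over the list alone (adjusted p = 0.000673, and adjusted p = 0.161 with an estimated correlation), Slc37a4, the glucose-6-phosphate transporter, being 1.38-fold lower. With a floor of 16 it was still lower (−0.53) but the call ended (adjusted p = 0.0648). Amino acid catabolism had 2 of 12 lower and 0 higher, or 4 and 1 adjusted over the list alone (adjusted p = 0.00292, and adjusted p = 0.329 with an estimated correlation). These were Tdo2 (1.56-fold, −0.65 ± 0.07) and Gpt (1.29-fold), whose call was lost without any of 8 samples (adjusted p up to 0.11), with no filter (0.0514), with the replicate block (0.0506) and with a floor of 16 (0.0641). De novo lipogenesis had 3 of 17 lower and 1 higher, or 3 and 2 adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.301 with an estimated correlation), with Mid1ip1 1.67-fold lower. Bile acid synthesis and sterol export had 2 of 13 lower and 0 higher, or 3 and 0 adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.283 with an estimated correlation). These were Cyp27a1 (1.44-fold) and Cyp7b1 (1.81-fold, lost without high-fat high-sugar replicate 1, adjusted p = 0.065). The xenobiotic list had 4 of 19 lower and 2 higher, or 6 and 2 adjusted over the list alone (adjusted p = 0.0404, and adjusted p = 0.329 with an estimated correlation), with Cyp2c29 1.94-fold lower and the receptors Nr1i2 1.46-fold and Nr1i3 1.53-fold lower. The dim Cyp2c29 probe averaged 50.2 in high-sugar and 10.5 in high-fat high-sugar samples. Of 4 other Nr1i3 probes 2 passed (−0.66 and −0.50) and 2 did not (−0.02 and −0.08). Gsta1 was 3.55-fold higher, and of its other probes 1 passed (1.32) and 1 did not (0.19). The clock list had 2 of 13 lower, Usp2 (2.38-fold) and Ciart, and 0 higher, or 3 and 0 adjusted over the list alone (adjusted p = 0.000566, and adjusted p = 0.217 with an estimated correlation). Lipid storage genes passed as higher, with 5 of 16 higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 0.000647, and adjusted p = 0.161 with an estimated correlation), among them Apoa4 (2.73-fold), Lpl (2.24-fold) and Plin2 (1.45-fold).

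The interaction asks where the sugar drink acted differently on the 2 diets. The sugar effect on Timp1 (2.65-fold, 1.40 ± 0.34), Il1b (2.44-fold) and Gpnmb (3.33-fold) was larger on the high-fat diet, and so was that on Jun (2.01-fold). That on Fgf21 (−1.54 ± 0.30), Acnat2 (−1.23 ± 0.27) and Mup20 (−1.83 ± 0.30) was lower on the high-fat diet. Here and below, larger and lower refer to the signed log2 change, so a lower effect can be a weaker rise, a reversal or a stronger fall. Fgf21 averaged 8.18 (log2) in control and 8.95 in high-sugar samples, but 10.24 in high-fat and 9.46 in high-fat high-sugar samples. In all, 270 genes passed, 127 with a higher and 143 with a lower sugar effect on the high-fat diet, and 121 by at least 1.5-fold (54 and 67). Which side was larger turned with cyclic loess (158 higher, 121 lower) and without control replicate 2 (149 and 148) or 4 (232 and 215), so it was not settled. Of the 270, the sugar effect itself passed on both diets for 53, on the high-fat diet alone for 104, on the normal diet alone for 113 and on neither for 0. The count was 160 without replicate 4 of the high-fat high-sugar group, 169, 174 and 447 without control replicate 1, 3 and 4, and 175 without high-sugar replicate 2.

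Other genes whose sugar effect differed most were Dct (3.03-fold), Plk3 (2.84-fold) and Cyp2a5 (2.27-fold), all larger on the high-fat diet, and Eif4ebp3 (−1.97 ± 0.53), the mitochondrial gene ND4L (−1.43 ± 0.19), Depp1 (−1.32 ± 0.34) and Acin1 (−1.29 ± 0.17), all lower. Cyp2b13 (1.795), Gsta1 (1.795), Mmp13 (0.97), A1bg (−1.84 ± 0.32) and Cyp2c29 (−0.58 ± 0.10) passed too, but 1 or 2 of the 4 groups averaged under the noise limit for each. Their values are therefore of intensity plus 32 and leave open on which diet the ratio of intensities was larger. With a floor of 16 they were 2.57, 2.59, 1.63, −2.93 and −1.55. The other probes of Acin1 (0.22) and Mmp13 (0.11) did not pass. Of others, 1 of 2 did for Gsta1 (1.32, against 0.39) and 3 of 4 for Cyp2a5 (1.01, 1.15 and 1.20, against 0.41). Adjusted p ran from 0.000103 (Acin1 and ND4L) to 0.0476 (Cyp2b13). The calls of Cyp2b13, Eif4ebp3, Gpnmb and Depp1 were lost without any of 19, 16, 13 and 13 of the 24 samples (adjusted p up to 0.0816, 0.0825, 0.0616 and 0.0684), and those of Dct and Il1b without control replicate 3 (adjusted p = 0.0543 and 0.0519). A floor of 16 ended these 6 calls and that of Timp1. The Gpnmb call was also lost with the replicate block (adjusted p = 0.0506), and those of Cyp2b13 and Eif4ebp3 with no filter (0.0567 and 0.0545) and with an offset of 64 (0.0574 and 0.0575).

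In the list of fatty acid oxidation genes and PPAR alpha targets, the sugar effect was lower on the high-fat diet for 3 of 26 members and higher for 0, or 6 and 0 adjusted over the list alone (adjusted p = 4.48e-05, and adjusted p = 0.867 with an estimated correlation). Besides Fgf21 these were Acot2 (−1.14 ± 0.29, other probes −0.03 and 0.00) and Hadha (−0.72 ± 0.19), whose calls were lost without any of 11 and 12 samples (adjusted p up to 0.069 and 0.0775) and with a floor of 16 (0.0695 and 0.0711). The Hadha call was also lost with no filter (0.0514). In the xenobiotic list it was higher for 4 of 19, Cyp1a2 (1.69-fold) among them, and lower for 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.0216, and adjusted p = 0.867 with an estimated correlation). The clock list had 0 of 13 members past the threshold in the interaction and 1 adjusted over the list alone, with a median of 0.43 (adjusted p = 0.0216, and adjusted p = 0.867 with an estimated correlation). Single members of other lists passed: Dgat2 (1.54-fold), Tdo2 (−0.45 ± 0.10), Pck1 (−0.58 ± 0.15), the stress factor Atf5 (−0.58 ± 0.15) and the erythroid gene Alas2 (0.64 ± 0.16). The calls of Pck1, Atf5 and Alas2 were lost without any of 12, 10 and 11 samples (adjusted p up to 0.0638, 0.0629 and 0.0624). A floor of 16 ended those of Pck1 (0.103) and Atf5 (0.0517), and Atf5 was also lost with the replicate block (0.0571) and with no filter (0.0534). Stellate and fibrosis markers had 2 of 13 higher (adjusted p = 0.0539) and macrophage markers 2 of 12 (adjusted p = 0.935).

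Both treatments together were compared with control (high-fat high-sugar against control). Lcn2 (7.06-fold) and the chemokine gene Ccl4 (4.62-fold, 2.21 ± 0.26, but 0.71 on another probe) were among the largest rises, and Cxcl10 (3.36-fold) and Saa3 (2.98-fold) also rose. Lpin1 was 8.92-fold lower (−3.16 ± 0.35), Thrsp 5.25-fold (−1.06, log2, on another probe), Scd1 3.48-fold and Acacb 2.12-fold. Gpnmb was 4.11-fold, Timp1 2.84-fold and Col1a1 1.86-fold higher. In all, 3945 genes changed, 2110 higher and 1835 lower, and 775 by at least 1.5-fold (494 higher, 281 lower).

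Further large changes against control were rises of Cyp2b9 (75.4-fold, 6.24 ± 0.60, with 5.63 at an offset of 64 and 7.19 at a floor of 16) and of Cyp2b23, Cyp2b13 and Gsta1, from under the noise limit to mean intensities of 772, 190 and 184, and falls of Hsd3b5 (11.0-fold lower, −3.46 ± 0.63, but −2.86 without high-fat high-sugar replicate 1), Cib3 (8.61-fold), Eif4ebp3 (6.67-fold) and Cyp4a12b (5.87-fold). For all 40 genes followed here, 6 of 6 samples lay on the same side of the control mean. Adjusted p ran from 3.13e-08 (Cyp2b9) to 0.000863 (Lcn2).

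Interferon-response genes rose with both treatments in 12 of 14 members and fell in 0, the same when adjusted over the list alone, with a median of 0.69 (adjusted p = 9.63e-06, and adjusted p = 0.265 with an estimated correlation), Gbp2 being 2.66-fold and Ifit3 2.35-fold higher. Macrophage markers had 8 of 12 higher and 0 lower, or 9 and 0 adjusted over the list alone (adjusted p = 0.000981, and adjusted p = 0.265 with an estimated correlation), with Lyz2 2.37-fold higher (0.36, log2, on another probe). Mpeg1 and Adgre1 rose from under the noise limit to mean intensities of 22.2 and 12.2, and a floor of 16 ended both calls, at 0.45 (adjusted p = 0.0589) and 0.11 (adjusted p = 0.152). Stellate and fibrosis markers had 6 of 13 higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.00309, and adjusted p = 0.411 with an estimated correlation), with Mmp13 up from under the noise limit to a mean intensity of 56.7 on 1 probe (−0.13, log2, on another). Acute phase genes had 10 of 17 higher and 1 lower, the same when adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.411 with an estimated correlation). Of 8 immediate early genes 5 rose and 0 fell, the same when adjusted over the list alone (adjusted p = 0.0321, and adjusted p = 0.411 with an estimated correlation), with Egr1 3.75-fold higher and Fos up from under the noise limit to a mean intensity of 27.5. The NRF2 list had 7 of 14 higher and 0 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.265 with an estimated correlation), with Srxn1 1.87-fold and Gclm 1.54-fold higher. The unfolded protein list had 6 of 17 higher and 1 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.411 with an estimated correlation), with Pdia6 1.58-fold higher and Atf3 up from under the noise limit to a mean intensity of 20.6. Beside these rises, 4 of 11 endothelial markers rose and 2 fell (adjusted p = 0.769).

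De novo lipogenesis fell with both treatments in 9 of 17 members and rose in 1, the same when adjusted over the list alone (adjusted p = 0.000981, and adjusted p = 0.265 with an estimated correlation), Elovl6 being 2.34-fold lower. Gluconeogenesis and glycogen had 9 of 13 lower and 1 higher, or 10 and 1 adjusted over the list alone (adjusted p = 0.000981, and adjusted p = 0.265 with an estimated correlation), with Pck1 1.90-fold, Pcx 1.84-fold (another probe 0.01) and Ppargc1a 1.69-fold lower. Amino acid catabolism and the urea cycle had 7 of 12 lower and 1 higher, the same when adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.543 with an estimated correlation), with Asl 1.93-fold and Ass1 1.52-fold lower. The clock list had 6 of 13 lower and 1 higher, the same when adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.411 with an estimated correlation), with Ciart 4.22-fold and Usp2 2.54-fold lower. Lipid storage genes had 8 of 16 higher and 3 lower (adjusted p = 0.0702), with Lpl 2.79-fold higher.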

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

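The tests of opposite second probes, of endothelial against fibrosis markers and of the fibrosis list without 1 sample, and the gene Tnfrsf12a in the set of 5 genes, were chosen only after the results were seen. So was the rule that fewer than 3 measured genes leave the clock test open.

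The sugar drink changed 3208 genes on the normal diet and 3399 on the high-fat diet. For each count 1 of 100 splits of the samples, the real one, gave as many, and the highest other gave 604 and 1278. A share of 1 in 100 is the lowest this test can give. A chance split is therefore unlikely but not excluded. A probe-level difference between the arrays of sugar and water samples may lie behind part of the calls: 69% of 1858 second probes of genes changed on the normal diet moved with the main probe (95% interval 66.8 to 71.1), between the bounds of 60% and 75% set before, which leaves it open as the whole source. Of the second probes that passed, 16.7% went the opposite way on the normal diet and 17.3% on the high-fat diet, against 0.424% and 1.71% for the high-fat diet with water and with sugar, as such a difference would give. A background shift is also open, since 11% of 21608 dim probes had an unadjusted p under 0.05 where chance gives 5%, although the share was 10.7% for the diets within the sugar-drink samples. Slides are not given in the sources used here, so a hybridisation difference and the drink itself, untested as a biological source, cannot be told apart for genes measured by 1 probe.

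Of genes picked for their interaction, 5 had values of 1.73 (Gpnmb), 1.40 (Timp1), 1.29 (Il1b), 0.97 (Mmp13, under the noise limit in 2 groups, 0.11 on its other probe) and 1.17 (Tnfrsf12a, SE 0.28, adjusted p = 0.0255), with 5, 5, 4, 6 and 2 of 6 high-fat high-sugar samples above all others, while the fixed stellate and fibrosis (adjusted p = 0.0539) and macrophage lists (adjusted p = 0.935) did not pass. A single high-fat high-sugar sample as the source stays open: 92% of the median interaction of 1.29 was left without replicate 2, but the 5 genes were picked as passing, and of the fibrosis list's median against high-sugar samples 72.3% was left without replicate 1 (0.44, bootstrap interval 0.21 to 0.67), under the bound of 75%. That bootstrap drew the list's 13 members and not the samples, so its interval does not measure the spread between samples. A lower share of hepatocytes would raise every other cell type alike. In high-fat high-sugar against high-sugar samples, the medians were 0.01 for 11 endothelial and 0.61 for 13 stellate and fibrosis markers. The difference of −0.60 was tested by shuffling genes between the lists (two-sided permutation test, 100000 resamples, p = 0.00211). Genes of a list move together (estimated correlation 0.121 and 0.298), so this p does not measure the spread between samples. In the fit across samples 0 of 11 endothelial and 7 of 13 stellate and fibrosis markers passed. An equal rise was therefore not seen, but the difference itself was not tested across samples, so this explanation is not excluded. Open too are a change within or in the number of stellate cells and macrophages, a hybridisation difference, and the treatments acting together, none of which was tested.

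With the high-fat diet and water 9 of 13 clock genes fell, Ciart at −2.69 and Per2 at −0.92 among them (adjusted p = 9.64e-07 for the list, and adjusted p = 0.0808 with an estimated correlation). A shift of clock phase may be behind this, and it would raise the genes of opposite phase. Of Arntl, Npas2, Clock and Cry1, Clock alone was above the noise, at 0.317 (SE 0.12, adjusted p = 0.0672, bootstrap interval over samples 0.08 to 0.58), so 1 gene does not decide it. Besides Clock, the list members Nr1d1 (−0.003, SE 0.176, adjusted p = 0.994), Nr1d2 (−0.145, adjusted p = 0.353) and Hlf (−0.01, adjusted p = 0.93) did not pass. Whether a phase shift would leave them unchanged was not tested. A difference in the hour of sampling between the groups, which the labels do not give, and an effect of the diet on the clock cannot be told apart.

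A chance split is also unlikely for the other counts, with the same limit of 1 in 100. The real split alone gave as many as the 1985 genes of the high-fat diet with water (highest other 75). The same held for the 873 with sugar (359) and the 3945 of both treatments (1346). For the 270 of the interaction, 1 of 100 rearrangements of residuals, the real one included, gave as many (highest other 2).

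A sample stood apart from the other 5 of its group for 22 of 405 gene and group pairs (5.43%), where chance gives about 5%. Each value here is the gap to the nearest sample over the group's range. In the control group these were replicate 4 for Cpt1a (high, 0.886) and Pdia6 (low, 0.749) and replicate 2 for Clec4f (high, 0.784) and Fgf21 (high, 0.733). In the high-sugar group they were replicate 1 for Cyp2b13 (high, 0.795), Nr1i2 (low, 0.781) and Pck1 (low, 0.74), replicate 2 for Clec4g (high, 0.68), Fos (high, 0.697) and Gpt (high, 0.688), replicate 5 for Mid1ip1 (low, 0.702) and Pdia6 (low, 0.664) and replicate 6 for Rgs16 (low, 0.647). In the high-fat group they were replicate 5 for Aatk (low, 0.668), Cyp2b9 (low, 0.658) and Cps1 (high, 0.6255), replicate 3 for Gsta1 (high, 0.658), replicate 2 for Srebf2 (low, 0.648) and replicate 6 for Vsig4 (low, 0.706). In the high-fat high-sugar group they were replicate 1 for Cyp1a2 (low, 0.785) and Srxn1 (high, 0.63) and replicate 2 for Atf5 (low, 0.658).

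The effect of the sugar drink differed between the diets, by the test of the interaction, for 28 of the 137 genes followed. Of the 242 pairs followed, 27 were of the interaction, named by their change or p in this same test. The count of 28 therefore follows largely from the selection and is no separate evidence. Of all 11115 genes, 2.43% passed this test. The difference was above 0 for Cyp2b13 (1.795), Gsta1 (1.795), Gpnmb (1.734), Dct (1.599), Plk3 (1.506), Timp1 (1.404), Il1b (1.287), Cyp2a5 (1.182), Jun (1.008), Mmp13 (0.971), Cyp1a2 (0.755), Alas2 (0.635) and Dgat2 (0.62). It was below 0 for Eif4ebp3 (−1.974), A1bg (−1.841), Mup20 (−1.829), Fgf21 (−1.54), ND4L (−1.429), Depp1 (−1.317), Acin1 (−1.289), Acnat2 (−1.232), Mup5 (−1.197), Acot2 (−1.14), Hadha (−0.715), Atf5 (−0.584), Cyp2c29 (−0.581), Pck1 (−0.575) and Tdo2 (−0.446). For Cyp2b13, Gsta1, A1bg, Mmp13 and Cyp2c29 at least 1 group averaged under the noise limit, so the direction holds for intensity plus 32 and is open for ratios of intensity.

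Of 3306 probes above the noise without 1 gene symbol, which no comparison of genes used, 829 changed with the sugar drink on the normal diet, 867 with it on the high-fat diet, 417 with the high-fat diet and water, 227 with the high-fat diet and sugar drink, 79 in the interaction and 952 with both treatments against control.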

How the results depend on the processing

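The offsets of 16 and 64, the floor of 16, cyclic loess on top of the deposited normalisation and the strict filter were chosen only after the data were seen. The counts of changed genes stayed within 1.5 times under every alternative run, samples left out aside, except these: all probes tested gave 5658, 5980, 3154, 1425, 509 and 6757 probes for sugar on the normal and high-fat diet, fat with water and sugar, interaction and both (more features tested), and array weights gave 450 in the interaction. The larger side turned with cyclic loess in the interaction (158 higher, 121 lower) and for fat with water (931, 1054), with array weights for fat with water (1000, 1006) and with all probes for fat with sugar (671, 754), and cyclic loess gave 2003 higher and 1310 lower for sugar on the high-fat diet. Lists called fell from 5, 4, 12, 14, 3 and 11 to 0 in each contrast with an estimated correlation. The estimates ran from 0.016 (NRF2 list) to 0.57 (amino acid list), all above the preset 0.01, and a higher correlation between members weakens the test. Beyond 1.5 times, lists called also numbered 8 and 9 without a filter for sugar on the normal and the high-fat diet, 5 for the interaction with the replicate block, 1 for the interaction with the floor of 16, and 2 for sugar on the high-fat diet with either cyclic loess or the strict filter. Among shifts within 1.5 times, fat with water gave 9 with either the floor or the strict filter. Fat with sugar gave 11 with the floor and 12 with the strict filter. Both treatments gave 10 with either and 14 without a filter. The cause of these other shifts was not tested. Leaving out each sample gave 2843 to 3216, 3003 to 3487, 1579 to 2109, 534 (without high-fat high-sugar replicate 1) to 956, 160 (without high-fat high-sugar replicate 4) to 447 (without control replicate 4) and 3588 to 3956 genes in that order, and the interaction also gave 169, 174 and 175 without control replicate 1 and 3 and high-sugar replicate 2. The correlation of sugar effects lay between 0.647 and 0.694 and that of high-fat effects between 0.479 and 0.555 under the other alternatives, and between 0.654 and 0.702 and between 0.489 and 0.549 with a sample left out. Of the 242 values of genes followed, out of 647 named by the rule, 213 kept call and direction under every alternative run for them. Calls were lost for 24 with the floor of 16, where 1 more, Adgre1 for sugar on the normal diet, had a value of 0, and for 7 without a filter, 4 with the block, 2 with offset 64, and 1 each with offset 16, without the trend and with the compared groups alone. None was lost with array weights, all probes, cyclic loess or the strict filter, which did not keep 7 of them. Leaving out 1 sample ended 164 of 5808 such calls and reversed 0. Values moved by over 1.5-fold in 5 cases with a sample left out, 10 with offset 16, 9 with offset 64, 42 with the floor and 0 otherwise. Planned but not run were no background correction, median scaling, cyclic loess in place of quantiles, a slide block, the detection p filter and an interaction fit on its own groups, since the values allow none or the fit would be the same. Signal near background limits dim genes, whose folds the offset shrinks.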

Other observations

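The gene lists and their test were planned before the data were seen, but the values and the probe filter they rest on were chosen after. No test was added in this part.

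Genes of glycolysis and fructose metabolism did not pass as a list in any contrast (lowest adjusted p = 0.263, with both treatments, where 4 of 9 fell and 0 rose). Ketohexokinase (Khk), which phosphorylates fructose, was lower with the sugar drink on the normal diet (−0.52 ± 0.16, SE, n = 6, adjusted p = 0.0148), and Tkfc, of the same pathway, was lower with the high-fat diet and water (−1.02 ± 0.15) and with the high-fat diet and sugar (−0.83 ± 0.15). Pgam1 was lower with sugar on both diets (−0.54 ± 0.08 and −0.36 ± 0.08). Of 18 genes of the mitochondrial respiratory chain, between 0 and 4 rose and between 1 and 2 fell in the simple contrasts (lowest adjusted p = 0.251), with Cox5b lower with sugar on both diets (−0.25 ± 0.07 and −0.25 ± 0.07).

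Of 15 sex-biased and growth hormone responsive genes, 9 fell and 3 rose with both treatments (adjusted p = 0.122), and the median of −0.20 and mean of 0.02 with sugar on the normal diet had opposite signs, as had −0.19 and 0.07 with the high-fat diet and water. Cyp2b9, of this list, rose with sugar on both diets, while the elongase Elovl3 was lower (−0.73 ± 0.19 and −0.66 ± 0.19). Among 11 markers of T, B and NK cells and antigen presentation, 2 rose with sugar on the high-fat diet (adjusted p = 0.57, median −0.05, mean 0.14), H2-Aa (from under the noise limit to a mean intensity of 11.9) and H2-Ab1 (0.63 ± 0.23), and 0 passed for either high-fat contrast. Of 3 cholangiocyte markers, Krt7 fell with sugar on the high-fat diet (−0.24 ± 0.08, list adjusted p = 0.282). Among 6 blood cell markers, the haemoglobin gene Hba-a1 did not pass (0.14 ± 0.11 with the high-fat diet and water), while in that contrast 2 rose and Alas2 fell (−0.69 ± 0.11, list adjusted p = 0.554). A median and mean of opposite sign were also found, among other lists, for lipid storage with sugar on the normal diet (−0.01 and 0.04, adjusted p = 0.872) and the unfolded protein list with the high-fat diet and sugar (0.09 and −0.05, adjusted p = 0.684).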
